A study of Equus caballus with 45 samples.

How the data were processed

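Small RNAs were sequenced from chorioallantois, endometrium and serum of mares with and without experimentally induced placentitis. Per the labels' protocols, tissue RNA was extracted with the RNeasy Mini Kit and had an RNA integrity number above 8.0, serum RNA was extracted with the miRNeasy Micro Kit, and libraries were made by an in-house ligation protocol whose adapters carry degenerate bases at the ligated ends, a design that lessens sequence preference of the ligase. The table deposited by the authors holds raw read counts, with 1 column per library and 1 row per small RNA. The aligner, the genome build, the annotation and any filter on reads are not given in the sources used here, and whether the degenerate bases were used to remove duplicate reads is not given either. PCR copies were therefore treated as reads, and counting intervals cover counting error only.

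The table has 716 rows and 45 libraries (32 from tissue, 13 from serum). By their names, 471 rows are equine miRNAs, 88 carry the name of a miRNA of another species, 68 are predicted miRNAs and 89 are other small RNAs. Empty cells (2032) were read as 0 beside 197 cells that hold an explicit 0, an assumption that the table itself does not settle. Marks in the table place 657 rows in a tissue set and 506 in a serum set, with 447 in both, and these marks were not used as a filter. A further 59 rows share number, letter and arm with another row under 29 names, so reads of near-identical sequences could have been split between them. Results for these rows, for the miR-8908 family, for miR-509a and miR-509b, for the miR-29b copies, for precursor and mature rows of miR-424 and miR-223, and for mmu-mir-1983 and mmu-miR-1983-3p are therefore uncertain as to the exact member. No reference genome was used, so no coordinates are given.

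Groups, regions and mare numbers were taken from the labels. The groups were 5 mares with subacute placentitis and 3 control mares, each with chorioallantois and endometrium at region 1 and region 2 and with serum, and 5 mares with acute placentitis, with serum. A number in a title was read as the mare within its disease group, so libraries of 1 group at 1 site are separate mares. Replicate libraries differed by far more than sampling noise (chi-square per degree of freedom from 36.8 to 2235 over 75 pairs), and none was counted as a repeat of another.

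Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, Benjamini-Hochberg adjustment over the rows tested, threshold of 0.05). Chorioallantois (16 libraries), endometrium (16) and serum (13) were fitted apart, each with 1 term per group and a shared spread. For the comparison of tissues, counts of both regions were summed per mare and tissue. Interaction terms tested whether a disease difference differed between regions or between tissues. Levels are given as counts-per-million (CPM) after TMM scaling, as mean ± SD, and fold changes as log2 ± standard error, the latter taken as the absolute log2 fold change divided by the square root of the F statistic. Adjusted p values of single small RNAs are from this test throughout. Where a group held 1 to 3 counts, the ratio of summed counts is given with its exact 95% counting interval, and a group with 0 counts was set to a floor of 3 counts over the group.

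Before the data were examined, 14 miRNA lists were fixed from general knowledge: NF-kB-responsive, leukocyte, erythroid, epithelial, ciliated epithelium, muscle, mesenchymal and matrix, endothelial, liver, the DLK1-DIO3 cluster, the miR-424/503/542 cluster, the miR-17 family clusters, let-7 and hypoxia (miR-210). Lists with at least 3 tested rows were compared with all other rows by camera in limma 3.58.1 with a preset correlation of 0.01, and adjusted over the lists of a comparison. Of 169 list tests, 48 passed with the preset correlation and 1 passed with a correlation estimated from the data, the DLK1-DIO3 cluster between the tissues. None of the 48 differed in sign between median, mean and test, while 24 of the 121 others did. The hypoxia list has 2 rows and was not tested. Lists overlap in part, since miR-155 is in both the leukocyte and the NF-kB-responsive list.

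The rule for naming small RNAs was also fixed before the data were examined. Per comparison it takes the 12 highest and 12 lowest log2 fold changes among those that passed with a mean of at least 10 CPM, members of the lists as examples, the 5 lowest p values where fewer than 3 passed, and the 5 most abundant small RNAs of each tissue. The rule leaves open which list members serve as examples, and these were picked after their values were seen, as were eca-miR-223-3p where its list did not pass and eca-miR-7-2-3p between endometrium regions.

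Alternatives chosen before the data were examined were RLE size factors, no filter on low counts, the Wald test of DESeq2 1.42.0, a fit of only the groups compared, each mare left out in turn, a replicate block and the estimated correlation. Added after seeing the data were a fit of miRNA rows only, limma-voom with sample quality weights, and fits without libraries that stood apart, namely region 1 chorioallantois of subacute mares 1 and 2, region 2 endometrium of control mare 2, and sera with most of their counts on other small RNAs. Regions and tissues of 1 mare are paired by the animal. Counts of rows without overlap were therefore compared with swaps within mares in those comparisons, a test added after seeing the data. Elsewhere they were set beside the mean count over chance splits of independent libraries. Rows can vary together, so single splits can lie far from that mean. The spread over splits was computed only for sera of all placentitis against control mares, where a mean of 3.83 went with up to 31. The mean correlation of deviations from the group means between libraries of the same mare was 0.225 and 0.250 for chorioallantois regions (subacute and control), 0.139 and 0.422 for endometrium regions, 0.206 and 0.331 for tissues at region 1, and 0.187 and 0.122 for tissues at region 2, with single pairs between -0.308 and 0.512.

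The test was checked on simulated counts drawn from the means and library sizes of these libraries, with 200 small RNAs changed per comparison. At a fold of 2, the share recovered was 29.0% in chorioallantois region 1 (subacute against control), 32.9% in endometrium region 1, 40.3% between chorioallantois regions, 25.4% between tissues, 6.06% in subacute serum and 13.2% between acute and subacute serum. At a fold of 8 the shares were 94.1%, 94.0%, 92.5%, 86.7%, 72.4% and 81.8%. The highest false share over the 13 comparisons was 4.58%. A raised list was called in 13 of 13 simulations and an unchanged list in 2 of 13, at an unadjusted camera p under 0.05. Simulated rows were drawn independently of each other. This check therefore does not show how the preset correlation performs for lists whose rows vary together. Libraries were also drawn without pairing by mare and without a library standing apart. The false share of the simulation is thus not that of the real comparisons. Figures were drawn with matplotlib 3.10.9.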

Results

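To compare small RNAs of the fetal membrane and the uterus in mares with and without induced placentitis, an inflammation of the placenta, 45 libraries were sequenced. The chorioallantois is the fetal side of the equine placenta and the endometrium is the maternal side. Both were sampled at region 1, the main lesion beside the cervical star where the membrane had separated, and at region 2, which was inflamed without separation. Control mares were sampled at matching sites. Tissue came from 5 mares with subacute placentitis and 3 control mares, and serum from these mares and from 5 mares with acute placentitis. The labels do not give the times that acute and subacute stand for. Total counts ranged from 236416 to 6531685 in chorioallantois (median 3293649.5, n = 16), from 513066 to 3363400 in endometrium (median 1814596.5, n = 16) and from 710166 to 2242158 in serum (median 1389561, n = 13). Between 650 and 700 rows were detected per chorioallantois library, 663 to 701 per endometrium library and 580 to 635 per serum library.

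The tissues and serum had different leading small RNAs. In chorioallantois the most abundant were eca-miR-125b-5p (8.49% ± 2.26 of counts, SD, n = 16), eca-let-7a-5p (5.51% ± 0.952), eca-miR-26a-5p (4.39% ± 0.657), the predicted ecaub_novel-mir-1178 (4.34% ± 1.26) and eca-miR-23a-3p (3.55% ± 0.477). In endometrium they were eca-let-7a-5p (7.33% ± 0.925, n = 16), eca-miR-26a-5p (5.25% ± 0.854), the epithelial eca-miR-200c-3p (5.24% ± 1.01), ecaub_novel-mir-1178 (4.98% ± 0.677) and eca-miR-125b-5p (3.96% ± 1.49). Serum was led by eca-miR-486-5p, which is abundant in red blood cells (15.4% ± 7.20, n = 13), and held the other small RNAs eca_sRNA_2043 (6.96% ± 6.44), eca_sRNA_2016 (5.61% ± 3.52) and eca_sRNA_2050 (5.15% ± 4.75) beside eca-miR-92a-3p (5.54% ± 1.93). Other small RNAs, meaning rows that are not named as miRNAs, took 33.8% ± 23.6 of the counts in acute serum, 24.3% ± 18.5 in subacute serum and 28.3% ± 12.04 in control serum.

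In chorioallantois at region 1, subacute mares had more of 2 small RNAs than control mares, and no other small RNA passed in either direction. The row named mmu-miR-5100-3p rose to 514.2 ± 183.3 CPM from 18.6 ± 7.94 (log2 fold change 4.79 ± 0.638, adjusted p = 0.00137) and was above every control in 5 of 5 mares. The other small RNA eca_sRNA_2005 rose from 3 counts over the 3 control libraries to 1181 counts over the 5 subacute libraries (ratio 323.1, counting interval 110 to 1569, adjusted p = 0.0276). eca-miR-223-3p, the leading miRNA of neutrophils, had 4417 ± 6001 CPM against 114 ± 70.6 (log2 5.27 ± 1.28, adjusted p = 0.113) and was above every control in 5 of 5 mares, yet did not pass. Its subacute libraries ranged from 639 CPM to 14766 CPM, the highest in subacute 1, where other small RNAs also took 9.21% of counts. The same held for eca-miR-142-3p of blood cells (69.8 CPM against 12.1, log2 2.52 ± 0.722, adjusted p = 0.133). The next lowest p values belonged to eca-miR-9097-3p (log2 5.00) and eca-miR-450c-5p (log2 2.29 ± 0.533), both at adjusted p = 0.112.

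By list at this site, the 15 NF-kB-responsive miRNAs, which inflammatory signals induce, had a median log2 fold change of 1.44 (camera adjusted p = 0.0154, and adjusted p = 0.458 with an estimated correlation). None passed singly or when adjusted over the list alone, with eca-miR-132-3p at 2.15, eca-miR-21-3p at 1.86, eca-miR-146a-5p at 1.63 and eca-miR-155-5p at 1.06. The 8 leukocyte rows had a median of 1.15 (adjusted p = 0.0154, and adjusted p = 0.458 with an estimated correlation), 3 rose when adjusted over the list alone and 0 of 8 over all small RNAs. Within it the lymphocyte miRNA eca-miR-150-5p was level (log2 -0.07 ± 0.249), while eca-miR-142-5p was at 1.24. The 9 rows of the miR-424, miR-503 and miR-542 cluster, an X-linked placental cluster, had a median of 0.51 (adjusted p = 0.0154, and adjusted p = 0.458 with an estimated correlation), with eca-miR-503-5p at 1.04 and 1 of 9 up over the list alone. Lower medians were found for 8 muscle rows (-0.67, adjusted p = 0.0154, and adjusted p = 0.458 with an estimated correlation) and for 16 epithelial rows (-0.38, adjusted p = 0.0351, and adjusted p = 0.653 with an estimated correlation), where none passed singly or over the list alone. Examples were the smooth muscle miRNAs eca-miR-145-5p (-0.82) and eca-miR-143-3p (-0.64), eca-miR-133a-3p (-1.22) and eca-miR-200c-3p (-0.61). The erythroid list did not pass (median 0.38, eca-miR-486-5p 0.26 ± 0.485), nor did the miR-17 family clusters (0.26, eca-miR-18a-5p 1.34), let-7 (-0.23, eca-let-7c-5p -0.85) or the others. Both rows of the hypoxia miRNA miR-210 were higher (median 0.70) and were not tested as a list.

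edgeR called 2 of 677 small RNAs at this site, 2 higher and 0 lower, with 66 higher and 44 lower at an unadjusted p under 0.05 (DESeq2 called 27, limma-voom 11). Groups did not overlap for 77 rows, of which 36 were higher in subacute mares, against a chance mean of 24.2 (3.57%). How far this count varies between splits was not computed, so it is no evidence of a disease effect by itself. Other small RNAs made up 4.18% ± 2.86 of counts in subacute and 2.07% ± 0.870 in control libraries (two-sided exact permutation p = 0.286, smallest possible 0.0179), and mean totals were 2087400 and 3309750. The call of eca_sRNA_2005 ended without control 1 (adjusted p = 0.301), control 2 (0.310), control 3 (0.152) or subacute 5 (0.0515), while its fitted log2 fold change lay between 7.94 and 9.05 in these fits (8.41 in the main fit). In all, 8 and 7 were called without subacute 3 and subacute 4, and 1 without both subacute 1 and 2. The list calls ended without control 2 (NF-kB-responsive 0.0566, leukocyte 0.0532, epithelial 0.162, the miR-424, miR-503 and miR-542 cluster 0.0532), control 1 (muscle 0.0959), control 3 (leukocyte 0.0677), subacute 1 (NF-kB-responsive 0.0653, epithelial 0.312), subacute 4 (NF-kB-responsive 0.148) or subacute 5 (epithelial 0.122). They also ended with no filter on low counts (leukocyte 0.0594, epithelial 0.0693), in a fit of only the groups compared (NF-kB-responsive and epithelial, both 0.0511) and without both subacute 1 and 2 at this site (epithelial 0.221).

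**Figure D1:**
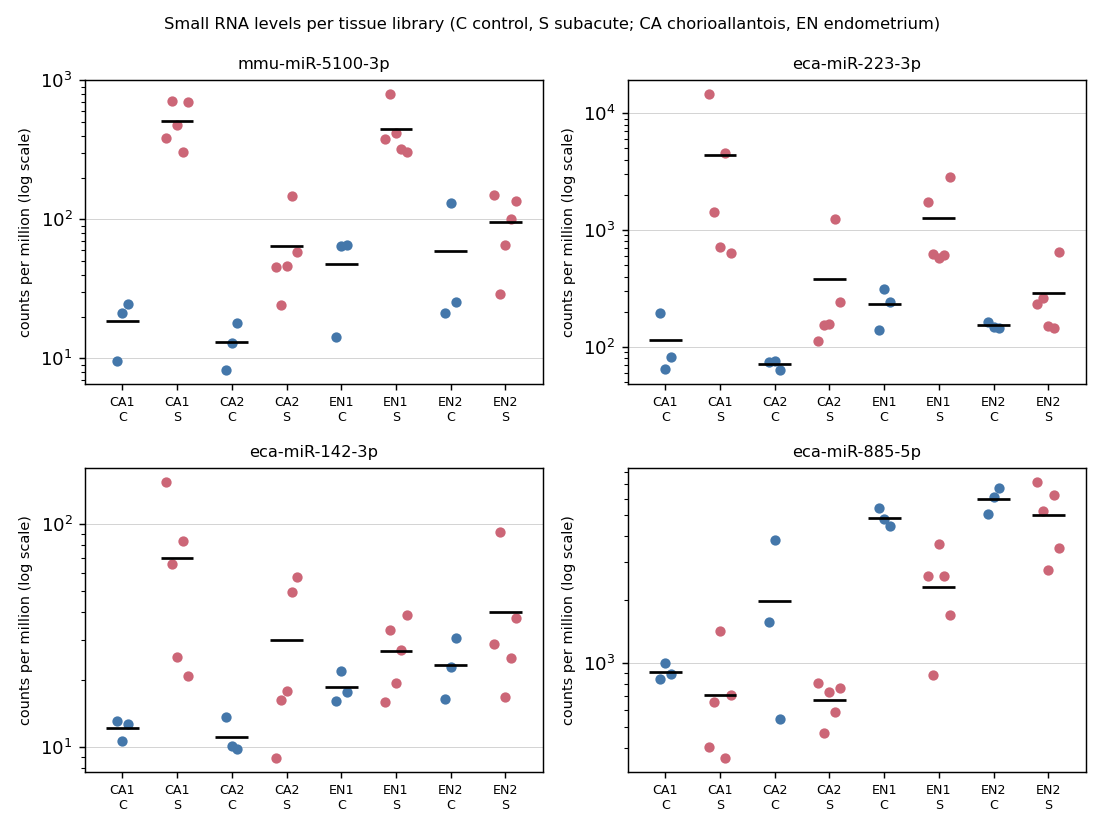
Levels of mmu-miR-5100-3p, eca-miR-223-3p, eca-miR-142-3p and eca-miR-885-5p in each tissue library, in CPM on a log axis, for control (C) and subacute (S) mares at chorioallantois (CA) and endometrium (EN) regions 1 and 2. Points are libraries and lines are group means; at chorioallantois region 1, mmu-miR-5100-3p was above every control in 5 of 5 subacute mares.

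In chorioallantois at region 2, no single small RNA passed, and the highest list median was that of miRNAs of red blood cells. The 7 erythroid rows had a median log2 fold change of 1.66, with eca-miR-486-5p at 1.66 ± 0.515 (21747 CPM against 6872, adjusted p = 0.177), eca-miR-451-5p at 1.36 and eca-miR-144-5p at 1.38. In 1 library, that of subacute 5, eca-miR-486-5p stood at 57742 CPM against 11625 to 14152 in the others. The endothelial miRNAs eca-miR-221-3p (-1.03) and eca-miR-222-3p (-1.15) were lower, as were the liver miRNAs eca-miR-122-5p (-1.61) and eca-miR-885-5p (-1.55), none of which passed. eca-miR-223-3p was at 2.43 ± 1.10 (adjusted p = 0.291), eca-miR-142-3p at 1.42 and mmu-miR-5100-3p at 2.30 (adjusted p = 0.129). The lowest p values belonged to eca-miR-431-5p of the DLK1-DIO3 cluster (1.27 ± 0.270), eca-miR-30c-5p (-1.17), eca-mir-424 (0.99) and eca-miR-503-3p (1.17), all at adjusted p = 0.115.

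At this site the erythroid list passed (camera adjusted p = 0.000286, and adjusted p = 0.182 with an estimated correlation), and 6 of 7 rose when adjusted over the list alone. The DLK1-DIO3 cluster, an imprinted cluster of maternally expressed miRNAs, was higher in 66 of 73 rows (median 0.32, adjusted p = 3.09e-05, and adjusted p = 0.354 with an estimated correlation), with eca-miR-370-3p at 1.01, eca-miR-487a-3p at 0.65 and 1 up over the list alone. Lower were the epithelial list (16 rows, median -0.62, adjusted p = 0.000165, eca-miR-200c-3p -0.53), the liver list (5 rows, -1.10, 0.00390, 1 down over the list alone), the endothelial list (5 rows, -1.03, 0.00747, 3 down over the list alone, eca-miR-126-3p -0.26) and the muscle list (8 rows, -0.42, 0.0246, eca-miR-145-5p -0.37). Each of these lower lists was at adjusted p = 0.354 with an estimated correlation. The leukocyte list had the next highest median after the erythroid list (1.12, with 7 of 8 rows higher) and did not pass (camera adjusted p = 0.0784). The NF-kB-responsive list did not pass either (median 0.65, camera adjusted p = 0.255). The mesenchymal and matrix list did not pass (median 0.27, adjusted p = 0.464), with 1 up and 2 down over the list alone (eca-miR-214-3p 1.30, eca-miR-29c-5p -0.72). edgeR called 0 of 677 small RNAs, with 66 higher and 45 lower at an unadjusted p under 0.05 and a lowest adjusted p of 0.115, while DESeq2 called 24 and limma-voom 2. Groups did not overlap for 80 rows, of which 55 were higher, against a chance mean of 24.2 whose spread over splits was not computed. Without subacute 1, 19 were called, and without control 3, 2 were called. The liver call ended without control 1 (0.0524) or control 2 (0.146) and with no filter on low counts (0.0551). The endothelial call ended without control 2 (0.0916), and the muscle call without control 3 (0.415), subacute 1 (0.0758), subacute 3 (0.05004) or subacute 4 (0.0969).

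In endometrium at region 1, 1 small RNA rose in subacute mares. eca_sRNA_2005 went from 3 counts over the control libraries to 353 counts over the subacute libraries (0.479 ± 0.442 against 42.4 ± 29.8 CPM, ratio 109, counting interval 37.0 to 530, adjusted p = 0.00267), above every control in 5 of 5 mares. mmu-miR-5100-3p had 446 ± 205.02 CPM against 48.1 ± 29.4 (log2 3.22 ± 0.748) and lay just outside the threshold at adjusted p = 0.0522, together with eca_sRNA_2058 (2.19), eca_sRNA_2024 (4.05), eca_sRNA_2045 (2.20) and eca-miR-7-2-3p (3.95). eca-miR-223-3p was at 2.46 ± 0.645 (1277 CPM against 232, adjusted p = 0.0989). The leukocyte list was higher in 8 of 8 rows (median 0.68, camera adjusted p = 0.00169, and adjusted p = 0.185 with an estimated correlation), 4 rose over the list alone, and eca-miR-142-5p (0.82) and eca-miR-342-5p (0.94) did not pass over all small RNAs. The liver list was lower in 5 of 5 rows (median -0.75, adjusted p = 0.00169, and adjusted p = 0.185 with an estimated correlation), with 2 down over the list alone, eca-miR-885-5p at -1.09 and eca-miR-122-5p at -1.28.

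The endothelial list at this site was lower in 5 of 5 rows (median -0.55, adjusted p = 0.0408, and adjusted p = 0.509 with an estimated correlation, eca-miR-221-5p -0.98). The epithelial list was lower in 12 of 16 (median -0.36, adjusted p = 0.0408, and adjusted p = 0.922 with an estimated correlation, eca-miR-429-3p -0.96, eca-miR-200a-3p -0.63), with 0 past the threshold over the list alone in either. The NF-kB-responsive list did not pass (median 0.20, adjusted p = 0.849), with eca-miR-146b-5p at 2.06. edgeR called 1 of 630, 1 higher and 0 lower, with 62 higher and 40 lower at an unadjusted p under 0.05 (DESeq2 called 16, limma-voom 15). Groups did not overlap for 63 rows, of which 37 were higher, against a chance mean of 22.5 whose spread over splits was not computed. The share of other small RNAs was 3.86% ± 0.973 in subacute and 2.20% ± 0.503 in control libraries (two-sided exact permutation p = 0.0714), and their totals averaged 1457760 and 2340080. The call of eca_sRNA_2005 held with each mare left out, while 4 were called without control 3, 3 without subacute 2 and 5 without subacute 3 or subacute 5. The epithelial call ended without any 1 of the 3 controls or subacute 1, 2 or 3 (adjusted p from 0.0527 to 0.252), the endothelial call without control 1 (0.114), control 3 (0.0579) or subacute 2 (0.162), and the leukocyte call without control 1 (0.0527). A fit of only the groups compared also ended the endothelial (0.0510) and epithelial (0.0697) calls, as did a fit of miRNA rows only (0.0632 and 0.104).

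In endometrium at region 2 no single small RNA passed. eca_sRNA_2005 had 39 counts over the subacute libraries against 3 over the control libraries (ratio 9.68, counting interval 3.08 to 49.0) and did not pass, nor did eca_novel_miRNA_1017 (-1.92), eca_sRNA_2058 (1.24), eca-miR-502-3p (1.04) or eca-miR-124-1-3p (-2.36), all at adjusted p = 0.972. The 5 rows of ciliated epithelium, miRNAs of multiciliated cells, had a median of 0.57 (camera adjusted p = 0.0190, and adjusted p = 0.669 with an estimated correlation), with eca-miR-34c-5p at 0.99. The DLK1-DIO3 cluster was lower in 44 of 59 rows (median -0.18, adjusted p = 0.00214, and adjusted p = 0.669 with an estimated correlation), with eca-miR-432-5p at -0.54, and over the list alone 0 passed in either list. eca-miR-223-3p was at 0.92. edgeR called 0 of 630, with 18 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. The ciliated epithelium call ended without control 2 (0.171), control 3 (0.0874), subacute 4 (0.106) or the control 2 library of this site alone (0.170), and the DLK1-DIO3 call without control 3 (0.567) or subacute 1 (0.0628).

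**Figure D2:**
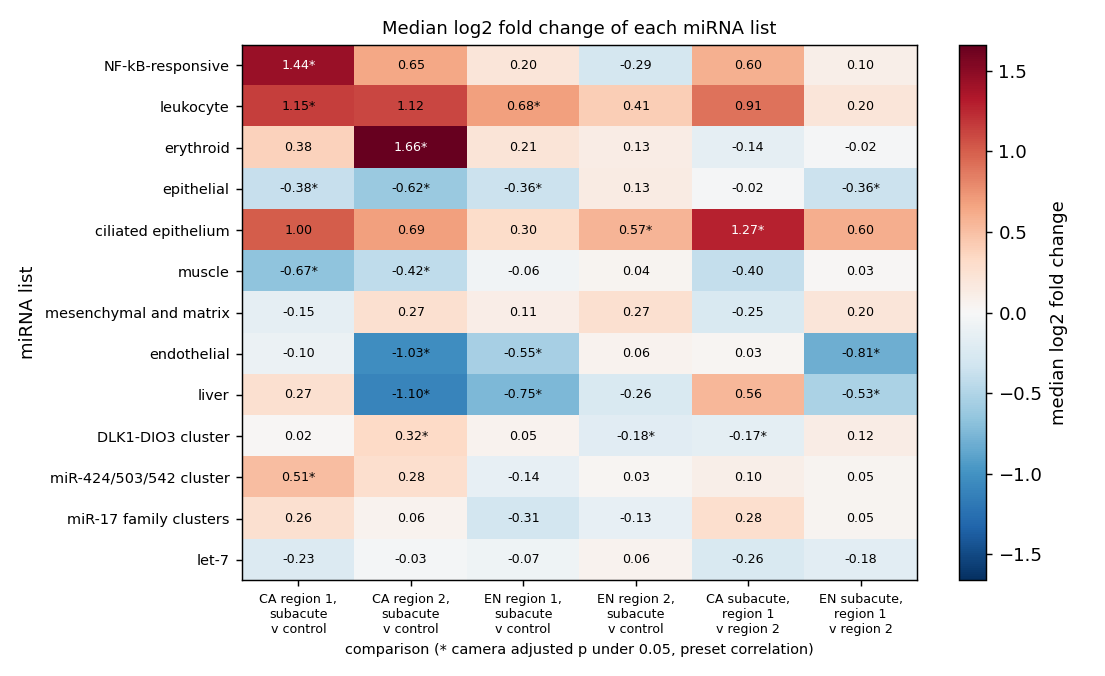
Median log2 fold change of each miRNA list (vertical axis) in 6 comparisons of chorioallantois (CA) and endometrium (EN), coloured from blue (lower) to red (higher), with a star where camera passed with the preset correlation. The erythroid list reached 1.66 in chorioallantois region 2 and was at 0.38 in region 1; with an estimated correlation none of the starred lists passed.

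Within subacute mares, region 1 of the chorioallantois, where the membrane had separated, was compared with region 2. mmu-miR-5100-3p rose at region 1 (514.2 ± 183.3 CPM against 64.0 ± 47.5, log2 3.01 ± 0.467, adjusted p = 0.00807), and every region 1 library was above every region 2 library. This fit did not pair the regions by mare, and the call ended with the mare as a block. eca-miR-223-3p was higher at 3.53 ± 0.938 without passing (adjusted p = 0.100), beside bta-miR-2355-3p (2.57), mmu-mir-1983 (3.52), ssc-miR-4332-3p (8.11, from 1 library at 7523 CPM) and efu-miR-9226-3p (1.62) at the same adjusted p. The leukocyte list had a median of 0.91 and did not pass with camera, with 1 up over the list alone and eca-miR-142-5p at 1.49. The ciliated epithelium list was higher in 4 of 4 rows (median 1.27, camera adjusted p = 0.0163, and adjusted p = 0.493 with an estimated correlation), 1 over the list alone, with eca-miR-34b-3p at 2.31 and eca-miR-34c-3p at 1.34. The level of eca-miR-34c-3p was low, at 8.88 CPM in subacute 1 at region 1 and 1.33 to 3.28 CPM in the other mares there. The region 1 library of subacute 2 held only 236416 counts. The DLK1-DIO3 cluster was lower in 48 of 73 rows (median -0.17, adjusted p = 0.0168, and adjusted p = 0.493 with an estimated correlation, eca-miR-370-5p -0.78), with 0 over the list alone. Other examples that did not pass were eca-miR-132-3p (1.65), eca-miR-214-3p (-1.39), eca-miR-133a-3p (-1.33), eca-miR-145-5p (-0.80) and eca-miR-486-3p (-0.93).

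edgeR called 1 of 677 between these regions, 1 higher, with 82 higher and 63 lower at an unadjusted p under 0.05 (DESeq2 29, limma-voom 4), and regions did not overlap for 22 rows. Over the other swaps of region within mares this count averaged 2 (0.295% of rows) and reached at most 10. With the mare as a block 0 were called, and mmu-miR-5100-3p stood at 3.22 (adjusted p = 0.0782). Its call also ended without subacute 2 (2.68, adjusted p = 0.0630), 3 (3.07, 0.0532) or 5 (2.94, 0.0665), and 7 were called without subacute 4. The ciliated epithelium call ended without subacute 3 (0.122) or 5 (0.0723). Without subacute 1, without the region 1 libraries of subacute 1 and 2, and in a fit of only the groups compared, 2 of its 4 rows were left and the list was not tested. The DLK1-DIO3 call ended without subacute 2 (0.0553), 3 (0.122) or 4 (0.190), with only the groups compared (0.0715), with miRNA rows only (0.0768) and without the region 1 libraries of subacute 1 and 2 (0.137).

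Between the endometrium regions of subacute mares, eca_sRNA_2005 rose at region 1 (42.4 ± 29.8 CPM against 4.26 ± 3.07, log2 3.32 ± 0.587, adjusted p = 0.0239), with all 5 region 1 libraries above all region 2 libraries. Not passing were eca_sRNA_2045 (1.94, adjusted p = 0.0677) and eca-miR-223-3p (2.14), eca-miR-885-3p (-1.49), eca_sRNA_2063 (1.92) and eca-miR-7-2-3p (2.56), all at adjusted p = 0.0789. The leukocyte list did not pass (median 0.20, adjusted p = 0.0848), with 2 up over the list alone. Lower lists were liver (5 of 5 rows, median -0.53, camera adjusted p = 0.000823, and adjusted p = 0.133 with an estimated correlation, 2 down over the list alone, eca-miR-885-5p -1.13, eca-miR-122-5p -0.53), epithelial (14 of 16, -0.36, 0.000823, and adjusted p = 0.501 with an estimated correlation, 0 over the list alone, eca-miR-429-3p -0.93, eca-miR-200a-3p -0.69) and endothelial (5 of 5, -0.81, 0.0129, and adjusted p = 0.467 with an estimated correlation, 3 down over the list alone, eca-miR-221-5p -1.08). edgeR called 1 of 630, 1 higher, with 71 at an unadjusted p under 0.05 (DESeq2 10, limma-voom 11), and regions did not overlap for 13 rows, where the other swaps of region within mares averaged 3.67 (0.582% of rows) and reached up to 17. With the mare as a block 5 were called, adding eca-miR-223-3p (2.05, adjusted p = 0.0113), eca_sRNA_2045 (1.87, 0.0113), eca-miR-7-2-3p and, lower, eca-miR-885-3p (-1.60, 0.0294). The call of eca_sRNA_2005 ended without subacute 1 (log2 2.97, adjusted p = 0.344) or 2 (3.34, 0.0978). In all, 6 were called without subacute 3 and 3 without subacute 5, and the endothelial call ended without subacute 2 (0.0590).

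Interaction terms asked whether the disease difference differed between the regions. In chorioallantois none passed: eca-miR-450c-5p was at 2.69, mmu-miR-5100-3p at 2.49, eca_novel_miRNA_1018 at -4.49, eca-miR-99a-2-5p at -0.82 and eca-miR-92a-5p at -1.88 (all at adjusted p = 0.848), and eca-miR-223-3p at 2.85. As lists, the difference was lower at region 1 for the erythroid miRNAs (median -1.40, camera adjusted p = 0.00623, and adjusted p = 0.440 with an estimated correlation, eca-miR-486-5p -1.40) and the DLK1-DIO3 cluster (-0.24, 0.00107, and adjusted p = 0.592 with an estimated correlation), and higher for the liver miRNAs (1.01, 0.0116, and adjusted p = 0.569 with an estimated correlation, eca-miR-122-5p 2.35). For the leukocyte list the difference between regions did not pass (median 0.08, camera adjusted p = 0.386). The liver call ended without control 2 (0.248) or subacute 3 (0.125), and the DLK1-DIO3 call without the region 1 libraries of subacute 1 and 2 (0.0542). edgeR called 0 of 677, with 33 at an unadjusted p under 0.05 (DESeq2 1, limma-voom 0), and 1 was called without control 3. In endometrium the 5 lowest p values were those of efu-mir-27a (1.81), eca_novel_miRNA_1017 (3.17, both adjusted p = 0.662), eca_sRNA_2045 (1.87), mmu-miR-5100-3p (2.47) and eca-miR-27a-5p (1.76, these 3 at adjusted p = 0.959). Its lists were lower at region 1 for epithelial (-0.58, 0.000294), endothelial (-0.75, 0.0220) and liver (-0.37, 0.0383) and higher for leukocyte (0.62, 0.0383), each at adjusted p = 0.361 with an estimated correlation. edgeR called 0 of 630, with 14 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Each endometrium list except epithelial lost its call with single mares left out: leukocyte without control 1, 3 or subacute 3, 4, 5 (adjusted p from 0.0574 to 0.278), endothelial without control 1, 2 or subacute 2 (0.0610 to 0.0840) and liver without control 1, 2, 3 or subacute 1, 2, 5 (0.0519 to 0.174). The liver call also ended with no filter (0.0968) and with miRNA rows only (0.0527). Leaving out the region 2 library of control 2 ended the liver (0.178) and endothelial (0.0975) calls.

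More small RNAs differed between the tissues than in any other comparison. In control mares eca-miR-506a-3p of the X-linked miR-506 to miR-514 cluster, which is not among the lists, had 771 ± 227 CPM in chorioallantois and 5.16 ± 1.93 in endometrium (log2 7.25 ± 0.470, adjusted p = 2.48e-08, n = 3), and eca-miR-433-3p of the DLK1-DIO3 cluster had 4053 ± 602 against 156 ± 9.08 (4.70 ± 0.371, adjusted p = 1.51e-07). The stratified-epithelium miRNA eca-miR-205-5p had 2072 against 49.3 CPM (5.40 ± 0.592, adjusted p = 2.36e-06). In the other direction, eca-miR-34c-5p had 2.72 ± 0.881 CPM in chorioallantois and 231 ± 76.0 in endometrium (-6.41 ± 0.648, adjusted p = 1.04e-06).

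Other high rows in chorioallantois were eca-miR-514a-5p (7.23), eca-miR-506a-5p (7.20), eca-miR-507a-3p (6.76), eca-miR-508-3p (6.46), eca-miR-514b-3p (6.23), eca-miR-509b-3p (7.34) and eca-miR-218-1-3p (5.16), along with eca-miR-509a-3p (880 against 2 counts over 3 mares, ratio 279, counting interval 77.0 to 2307) and eca-miR-509a-5p (1097 against 3, ratio 232, 79.1 to 1126). Lowest in chorioallantois were eca-miR-34b-5p (2 against 256 counts, endometrium over chorioallantois 202, interval 55.3 to 1676), eca-miR-208a-3p (-7.28 ± 2.82), eca-miR-34b-3p (-6.50), eca-miR-34c-3p (-6.22), eca_novel_miRNA_1012 (-4.82), eca-miR-490-5p (-4.64), eca-miR-204b-2-3p (-3.67), eca_sRNA_2003 (-3.65), eca-miR-449a-5p (-3.64), eca-miR-490-3p (-3.32) and eca-miR-29b-2-5p (-3.15, adjusted p = 9.95e-08). The DLK1-DIO3 cluster rose in 69 of 73 rows (71 over the list alone), with a median of 2.25 (camera adjusted p = 1.17e-31, and adjusted p = 0.0356 with an estimated correlation), among them eca-miR-431-5p (2.58) and eca-miR-370-3p (3.21). The miR-424, miR-503 and miR-542 cluster rose in 9 of 9 (median 2.52, adjusted p = 0.000127, and adjusted p = 0.0773 with an estimated correlation), with eca-miR-542-5p at 3.11, eca-miR-503-3p at 2.78 and eca-miR-424-5p at 1.49.

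Higher in endometrium were the ciliated epithelium list (5 of 5 rows, median -6.41, adjusted p = 3.13e-06, and adjusted p = 0.0773 with an estimated correlation), the endothelial list (5 of 5, -1.48, 0.0123, and adjusted p = 0.295 with an estimated correlation, eca-miR-126-3p -1.42, eca-miR-221-3p -1.48) and the liver list (5 of 7, 6 over the list alone, -1.68, 0.0115, and adjusted p = 0.303 with an estimated correlation, eca-miR-192-5p -1.68, eca-miR-122-5p -1.58). The mesenchymal and matrix list passed as lower in chorioallantois (median -1.39, adjusted p = 0.0329, and adjusted p = 0.434 with an estimated correlation), but its 12 rows went both ways: 4 rose, among them eca-miR-214-3p (2.02), and 7 fell, all of the miR-29 family, which targets collagens, such as eca-miR-29c-3p (-2.89). The remaining lists did not pass. Of 15 NF-kB-responsive rows 2 were higher and 4 lower in chorioallantois (eca-miR-21-5p -2.41), of 8 leukocyte rows 0 and 2 (eca-miR-150-5p -1.42), of 7 erythroid rows 0 and 3 (eca-miR-451-5p -1.57), of 16 epithelial rows 1 and 7 (eca-miR-141-3p -1.57, eca-miR-200c-3p -0.89) and of 8 muscle rows 2 and 1 (eca-miR-133a-3p 2.52, eca-miR-1-1-3p 1.90), while eca-miR-145-5p was at 0.13. Over the list alone these counts were the same except for muscle, with 2 and 0. Of 19 miR-17 family rows 0 were higher and 2 lower (eca-miR-17-5p -0.03 ± 0.308, not passing), and of 12 let-7 rows 1 and 3, with a median of -0.08, a mean of 0.71 and eca-let-7c-5p at 2.39. Both miR-210 rows were higher without passing (median 0.49).

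edgeR called 318 of 687 rows between the tissues, 179 higher and 139 lower in chorioallantois, with 365 at an unadjusted p under 0.05. The tissues did not overlap for 387 rows, where the other swaps of tissue within mares averaged 24 (3.49% of rows) and reached at most 31. With the mare as a block 341 were called, 302 of them shared with the main fit. The block ended the call of eca-miR-208a-3p (-0.17, adjusted p = 0.967). That miRNA rested on control 3, without which it was at 2.26 (adjusted p = 0.510), and its call also ended without control 1 (0.0709) or control 2 (0.0939), with only the groups compared (0.0759) and with limma-voom (0.455). Its log2 fold change was -7.97, -7.74, -7.20 and -2.33 there. Further calls ended for eca-miR-1-1-3p without control 1 (log2 1.10, adjusted p = 0.154), eca-miR-451-5p without control 2 (-1.26, 0.105), eca_sRNA_2003 without control 2 (-3.54, 0.0501), eca-miR-122-5p without control 2 (-1.63, 0.0535) or 3 (-0.81, 0.224), and the mesenchymal and matrix list without control 2 (0.0670) or with only the groups compared (0.0550).

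Whether disease differences differed between the tissues was tested with an interaction term, and no single small RNA passed. The lowest p values were those of eca-miR-29b-2-5p (-1.31, adjusted p = 0.138) and eca-miR-431-5p (1.68, adjusted p = 0.175), followed by ecaub_novel-mir-1155 (3.22), eca-miR-200c-3p (-0.78) and eca-miR-15b-3p (1.27). As lists the difference was higher in chorioallantois for the DLK1-DIO3 cluster (median 0.31, camera adjusted p = 1.51e-05), NF-kB-responsive (0.59, 0.0108), erythroid (1.28, 0.0332, eca-miR-486-5p 1.29, eca-miR-451-5p 1.28), miR-424, miR-503 and miR-542 (0.43, 0.0332, eca-miR-503-5p 1.20) and miR-17 family (0.34, 0.0332) lists and lower for the epithelial list (-0.35, 0.00346). Each was at adjusted p = 0.476 with an estimated correlation, and eca-miR-223-3p was at 2.27. Over the list alone, 1 DLK1-DIO3 row was up, 1 epithelial row was down and 0 passed in the other 4. edgeR called 0 of 687, with 44 at an unadjusted p under 0.05, and DESeq2 called 3 and limma-voom 0. With the mare as a block the erythroid (0.0532), miR-424, miR-503 and miR-542 (0.0534) and miR-17 family (0.0534) calls ended. With miRNA rows only the erythroid and miR-17 family calls ended (both 0.0524). Of the 6 list calls, that of the DLK1-DIO3 cluster held with each mare left out, and the epithelial call ended without control 1 (0.0670). The other 4 ended without control 1, 2 or 3 or subacute 1, 2, 3, 4 or 5, in different sets for each list (adjusted p from 0.0539 to 0.352).

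In serum of subacute mares no single small RNA passed against controls. The 5 lowest p values belonged to eca-miR-7-2-3p (2.14), eca-miR-598-3p (-2.03), eca-miR-381-3p (-1.62), eca-miR-9a-3p (-1.74), all at adjusted p = 0.999, and the predicted ecaub_novel-mir-28, with 14 counts over 5 mares and 0 over 3 controls (at least 2.29-fold higher against a floor of 3 counts over the group). The epithelial list was higher in 11 of 13 rows (median 0.74, camera adjusted p = 0.00258, and adjusted p = 0.570 with an estimated correlation, eca-miR-200c-3p 0.75), and the liver list in 7 of 7 (0.57, 0.0393, and adjusted p = 0.570 with an estimated correlation, eca-miR-192-5p 0.61). The DLK1-DIO3 cluster was lower in 32 of 39 rows (-0.63, 0.00258, and adjusted p = 0.798 with an estimated correlation), and over the list alone 0 passed in any of these. eca-miR-223-3p was level at 16271 ± 4850 and 16239 ± 3120 CPM. edgeR called 0 of 547, with 11 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The liver call ended without control 2 (0.369), control 3 (0.171), subacute 2 (0.363) or subacute 5 (0.0667), with no filter (0.222), with miRNA rows only (0.0542) and without the sera led by other small RNAs (0.0556). The epithelial call ended without control 2 (0.286) or subacute 2 (0.0633), and the DLK1-DIO3 call without control 1 (0.355) or subacute 1 (0.424).

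In serum of acute mares no single small RNA passed against controls. eca-miR-192-5p, a miRNA of liver and gut, had 1343 ± 489 CPM against 4306 ± 1410 (log2 -1.68 ± 0.417, adjusted p = 0.175) and was below every control in 5 of 5 mares. eca-miR-215-5p (-1.87), eca-miR-7-2-3p (2.92) and eca-miR-8908j-5p (3.96) had the same adjusted p, and ecaub_novel-mir-28 had 51 counts over 5 mares and 0 over 3 controls (at least 11.7-fold higher against a floor of 3 counts over the group). The muscle miRNA eca-miR-133a-3p was at 3.38 ± 0.980, eca-miR-145-5p at 2.64, eca-miR-885-5p at 3.31 (all 3 at adjusted p = 0.208), eca-miR-142-5p at -1.06 and eca-miR-223-3p at 0.19 ± 0.471. No list passed, the nearest being muscle (median 1.60, camera adjusted p = 0.0705) with 2 up over the list alone and DLK1-DIO3 (-0.60, 0.0705) with 0. Over the liver list alone 1 was up and 2 were down. edgeR called 0 of 547, with 51 at an unadjusted p under 0.05, while DESeq2 called 11 and limma-voom 0. Groups did not overlap for 19 rows, against 19.5 by chance. Without the sera led by other small RNAs 13 were called, and without acute 4, 1 was called.

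Between acute and subacute serum, 4 miRNAs changed. eca-miR-133a-3p of skeletal and heart muscle rose to 2821 ± 2655 CPM from 133.2 ± 32.03 in subacute serum (log2 4.40 ± 0.831, adjusted p = 0.0130), with 5 of 5 acute mares above every subacute mare. eca-miR-8908j-5p rose to 176 ± 176 from 10.7 ± 3.37 (4.02 ± 0.840, adjusted p = 0.0277), in 4 of 5 acute mares. eca-miR-192-5p fell to 1343 ± 489 from 6579 ± 1600 (-2.29 ± 0.386, adjusted p = 0.0115) and eca-miR-215-5p, which shares its seed, to 107.5 ± 29.2 from 583 ± 259 (-2.44 ± 0.451, adjusted p = 0.0130), each in 5 of 5 acute mares. Not passing were eca-miR-9a-3p (2.74, adjusted p = 0.0624), eca-miR-145-5p (2.38), eca-miR-200b-5p (-1.62, both adjusted p = 0.0938), eca-miR-885-5p (2.82), eca-miR-143-3p (1.70), eca-miR-150-5p (-1.27) and eca-miR-7-2-3p (0.77).

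The muscle list was higher in acute serum (8 rows, median 1.56, camera adjusted p = 0.00399, and adjusted p = 0.405 with an estimated correlation), with 1 up over all small RNAs and 4 over the list alone. The liver list was lower (7 rows, -1.43, 0.000160, and adjusted p = 0.149 with an estimated correlation), with 2 down over all small RNAs and 1 up and 4 down over the list alone. The 2 down over all small RNAs are eca-miR-192-5p and eca-miR-215-5p, already named above. Of the 7 rows 2 were higher, eca-miR-885-5p among them. The leukocyte list (9 rows, -0.39, 0.0115, and adjusted p = 0.247 with an estimated correlation) and the epithelial list (13 rows, -0.39, 0.0115, and adjusted p = 0.560 with an estimated correlation) were lower, each with 2 down over the list alone. edgeR called 4 of 547, 2 higher and 2 lower, with 64 at an unadjusted p under 0.05 (DESeq2 24, limma-voom 2). Groups did not overlap for 18 rows against a chance mean of 4.34, whose spread over splits was not computed. With 1 mare left out at a time eca-miR-192-5p was called in all 10 fits, eca-miR-133a-3p ended without subacute 2 (0.0519) or 4 (0.0502), eca-miR-215-5p without subacute 2 (0.0519) and eca-miR-8908j-5p without acute 3 (0.0802), acute 5 (0.0523) or any 1 subacute mare (0.0603 to 0.0986). Where these calls ended, the log2 fold change was 4.41 and 4.48 for eca-miR-133a-3p, -2.13 for eca-miR-215-5p and 3.26 to 4.17 for eca-miR-8908j-5p. The count was 14 without acute 4, 1 without subacute 2, 2 without subacute 4 and 7 without the sera led by other small RNAs, and list calls ended for epithelial without acute 2 (0.159), acute 4 (0.138) or subacute 2 (0.0786) and for leukocyte without subacute 5 (0.0606) or the sera led by other small RNAs (0.0909).

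**Figure D3:**
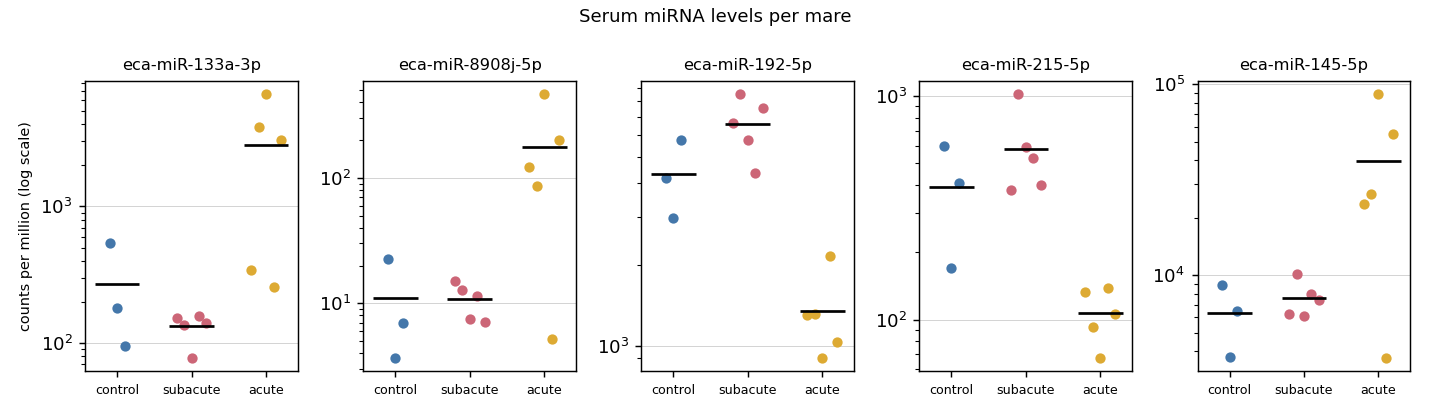
Levels of eca-miR-133a-3p, eca-miR-8908j-5p, eca-miR-192-5p, eca-miR-215-5p and eca-miR-145-5p in serum of each mare, in CPM on a log axis whose range differs between panels. Points are mares and lines are means of the control, subacute and acute groups; eca-miR-192-5p was lower in 5 of 5 acute mares than in every subacute mare.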

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

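The tests for a class-wide rise of other small RNAs and for dilution of serum miRNAs were written before their results were seen. The other tests in this part were set only after the results were seen. They are those that leave a mare out, the blood and leukocyte tests and the test of library composition. The fits without a mare and the estimated correlation had been chosen before, but not their use as tests of these explanations.

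mmu-miR-5100-3p and eca_sRNA_2005 were higher at region 1 of subacute mares. Rows of other small RNAs had a median log2 fold change of 0.448 in chorioallantois region 1 (SD 1.49 over 77 rows). This compares with 4.79 for mmu-miR-5100-3p, with 2 rows above it. That row was named for its low p value, so a class median below it was likely beforehand. By its name it also belongs to the miRNAs of another species, a class that was not tested. A class-wide rise from broken-down longer RNA was therefore not decided there. In endometrium region 1 the median of other small RNA rows was 0.72 (SD 0.870 over 72 rows), against 3.22 for mmu-miR-5100-3p and 6.39 for eca_sRNA_2005. The written test did not cover this site, and the class had 3.86% of counts against 2.20% in controls, so a class-wide part stays open. Without subacute replicate 1, whose share of other small RNAs in chorioallantois region 1 was highest, the number called there against controls was still 2, which argues against 1 library standing apart as the sole cause at that site. Against controls in endometrium region 1, eca_sRNA_2005 was still called without that mare (adjusted p = 0.0145). Between endometrium regions its call ended (adjusted p = 0.344), so the call depended on that mare. The log2 fold change there stayed at 2.97 against 3.32, and every region 1 library lay above every region 2 library. These values argue against that mare as the sole cause of the difference in eca_sRNA_2005. Subacute libraries at region 1 were also shallower on average, no genome was used to check what these rows are, and separation of the membrane remains an untested biological explanation.

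eca-miR-223-3p and eca-miR-142-3p were higher in chorioallantois region 1 of subacute mares without passing. Leaving out subacute replicate 1 left eca-miR-223-3p at a log2 fold change of 4.10 (adjusted p = 0.0927), which argues against that library as the sole cause. Blood left in the tissue could not be excluded: miR-486-5p was higher by 2354 CPM (SE 2119). This is 5.82% of the 40448 CPM expected at the mean ratio of both miRNAs in control serum (9.40 ± 6.90, n = 3). It is 34.8% at the lowest ratio of 1.57, and 66.1% with 1 SE added. Serum stood in for whole blood, whose cells it lacks, so these shares do not measure blood left in the tissue. A candidate source is leukocytes in the tissue, which these tables leave open, since the leukocyte list was at adjusted p = 0.458 with an estimated correlation. Of its 8 rows, 7 had a control mean of at least 10 CPM and 1 is also in another list, and of its most abundant members in controls eca-miR-155-5p was at 2730 CPM against 1308, eca-miR-150-5p at 1168 against 1222 and eca-miR-342-3p at 656.1 against 640.2.

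The levels of 4 serum miRNAs differed between acute and subacute mares. Leaving out all rows of other small RNAs before scaling kept 4 of these calls, so the calls did not depend on those rows being counted. TMM scaling already adjusts for such a class in both fits, so this comparison cannot decide on the composition of the libraries as the cause. Composition among the miRNAs themselves was not tested. On the scale of total counts the median log2 ratio over 547 rows was -0.275, short of the shift set in the test for dilution by other RNA. TMM scaling already removes a shift shared by all rows, so this test has no bearing on the 4 calls. With 1 mare left out at a time the lowest number of calls was 1, always including eca-miR-192-5p, while eca-miR-8908j-5p was lost in 7 of 10 fits. Stage of disease, handling of the sera and the mares themselves differ together between these groups and stay open as untested.

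Quantities were checked 1 at a time in groups of 5 libraries. In 23 of these checks (16.2%) 1 library lay far from the others. Chance gives about 1 in 20 (7.1) for normally distributed values of rows that were not picked by their values. Neither was met for certain: the distribution was not checked, and some rows were named after their values were seen. The same libraries also recur (7 of the 23 are subacute 1 in chorioallantois region 1), so the excess was not tested. The value given for each is the gap to the nearest library as a share of the range of the group. In subacute mares at chorioallantois region 1, subacute 2 had the fewest rows detected (0.840, 650 against 692 to 700) and the highest eca-miR-18a-5p (0.844, 164 CPM against 31.04 to 51.8). Subacute 1 there had the highest share of other small RNAs (0.794, 9.21% against 2.19% to 3.63%) and the highest eca-miR-223-3p (0.724, 14766 CPM against 639 to 4537), eca-miR-34c-3p (0.741, 8.88 against 1.33 to 3.28), eca-miR-7-2-3p (0.731, 234 against 6.21 to 67.4), eca-miR-9097-3p (0.832, 54.1 against 2.24 to 10.96), mmu-mir-1983 (0.915, 247 against 22.97 to 42.1) and ssc-miR-4332-3p (0.998, 7523 against 10.6 to 26.6). At the same site subacute 5 was highest in eca-miR-133a-3p (0.766, 754 against 89.3 to 245) and eca-miR-214-3p (0.723, 13125 against 4576 to 6940), and subacute 4 in eca-miR-503-5p (0.759, 1741 against 607 to 879).

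At chorioallantois region 2, subacute 4 had the lowest total (0.895, 2123291 against 3608185 to 3782315) and the highest eca-miR-222-3p (0.829, 2595 CPM against 1206 to 1444), eca-miR-223-3p (0.885, 1247 against 112 to 243) and mmu-miR-5100-3p (0.722, 146.2 against 24.1 to 58.0). Subacute 5 had the highest eca-miR-486-5p (0.945, 57742 against 11625 to 14152). In endometrium, subacute 5 was highest in eca-miR-146b-5p at region 1 (0.867, 1448 against 98.5 to 278) and in eca-miR-223-3p at region 2 (0.772, 655.1 against 145.8 to 262). At region 2, subacute 3 was highest in eca-miR-124-1-3p (0.727, 24.9 against 3.25 to 9.16) and subacute 1 lowest in eca_sRNA_2063 (0.767, 15.99 against 29.5 to 33.6). In serum, subacute 3 was lowest in eca-miR-133a-3p (0.717, 78.2 against 135.9 to 159) and subacute 2 highest in eca-miR-143-3p (0.765, 233 against 68.3 to 107).

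Differences between regions or tissues in the disease effect passed for 13 lists by an interaction term with the preset correlation, and for 0 of them with an estimated one. Between chorioallantois regions these were erythroid (camera adjusted p = 0.00623), liver (0.0116) and the DLK1-DIO3 cluster (0.00107). Between endometrium regions they were leukocyte (0.0383), epithelial (0.000294), endothelial (0.0220) and liver (0.0383). Between the tissues they were NF-kB-responsive (0.0108), erythroid (0.0332), epithelial (0.00346), the DLK1-DIO3 cluster (1.51e-05), the miR-424, miR-503 and miR-542 cluster (0.0332) and the miR-17 family clusters (0.0332).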

How the results depend on the processing

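Fits of miRNA rows only, limma-voom with quality weights and fits without libraries that stood apart were chosen after seeing the data, and the rest before. RLE size factors kept every count of calls within 1.5 times. DESeq2 called 27 in chorioallantois region 1 (2 shared with edgeR), 24 in region 2, 16 in endometrium region 1, 29 and 10 between chorioallantois and endometrium regions, 1 in the chorioallantois interaction, 3 in the tissue interaction, 11 in acute serum against control and 24 in acute against subacute serum (4 shared). In the same order limma-voom called 11, 2 and 15, then 4 and 11 between regions, and 2 in acute against subacute serum (2 shared). With miRNA rows only, 1 was called in chorioallantois region 1, 0 in endometrium region 1 and 0 between endometrium regions, since this setting leaves out eca_sRNA_2005, the other small RNA called in each. A fit of only the groups compared called 3 between endometrium regions. Without libraries that stood apart 1 was called in chorioallantois region 1, 2 in endometrium region 1, 13 in acute serum against control and 7 in acute against subacute serum. With 1 mare left out at a time the counts ranged from 1 to 8 in chorioallantois region 1, 0 to 19 in region 2, 1 to 5 in endometrium region 1, 0 to 7 and 0 to 6 between chorioallantois and endometrium regions, 0 to 1 in the chorioallantois interaction, 238 to 307 between tissues, 0 to 1 in acute serum against control and 1 to 14 in acute against subacute serum. Where these counts moved, fewer libraries or fewer tests enter by construction, and otherwise the cause was not tested.

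A replicate block by mare called 0 between chorioallantois regions, where mmu-miR-5100-3p was lost (adjusted p = 0.0782), and 5 between endometrium regions, where eca_sRNA_2045 (0.0113), eca-miR-223-3p (0.0113), eca-miR-885-3p (0.0294) and eca-miR-7-2-3p were gained. Between tissues it called 341, of which 302 were among the 318 of the main fit, and of the small RNAs named there it ended eca-miR-208a-3p. It also ended 3 lists of the tissue interaction, and beyond these it changed the call of no list or named small RNA within mares. Numbers of mares in different disease groups mark different animals, and deviations of equal numbers had mean correlations of -0.150, -0.0206, -0.194 and -0.239 at the 4 tissue sites and -0.156, -0.0660 and 0.0704 in serum. With that number as a block 3 were called in chorioallantois region 1 and 0 in acute against subacute serum, where the log2 fold changes of eca-miR-133a-3p, eca-miR-8908j-5p, eca-miR-215-5p and eca-miR-192-5p were 4.14, 3.46, -2.46 and -2.34 (adjusted p from 0.133 to 0.247), against 4.40, 4.02, -2.44 and -2.29 in the main fit. The list calls of NF-kB-responsive (0.0686) and epithelial (0.185) in chorioallantois region 1, ciliated epithelium in endometrium region 2 (0.668) and liver in subacute serum (0.162) ended. Of the 48 lists called, 1 was called with an estimated correlation, the DLK1-DIO3 cluster between tissues.

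Over all settings, list results were kept in 488 settings and lost in 167. In 3 further settings the ciliated epithelium list between chorioallantois regions had 2 rows left and gave no value: without subacute 1, with only the groups compared and without libraries that stood apart. Of the losses, 47 came with the estimated correlation, 5 with no filter, 6 with only the groups compared, 7 with miRNA rows only, 7 with the block, 8 without libraries that stood apart and the rest with a mare left out. Results of named small RNAs were kept in 2487 of 2650, lost in 38, reversed in 19 and gained in the rest. Each reversal was near 0 in the fit reported except that of eca-miR-208a-3p, and the cause was not tested. eca-miR-208a-3p between tissues ranged from -7.97 to 2.26 with 1 mare left out, the latter without control 3. eca-miR-150-5p in chorioallantois region 1 was at 0.0171 with no filter, 0.0127 with only the groups compared, 0.0428 with miRNA rows only, and 0.169, 0.0642, 0.0716 and 0.115 without control 2 and subacute 2, 3 and 5 (range -0.201 to 0.169). eca-miR-17-5p between tissues was at 0.00575 with no filter and 0.300 without control 3 (range -0.223 to 0.300). eca-miR-223-3p in subacute serum against control was at -0.00357 with RLE, -0.00333 with DESeq2, -0.137 with limma-voom, -0.0937 without sera led by other small RNAs, and -0.292, -0.102 and -0.119 without control 1 and subacute 1 and 5 (range -0.292 to 0.123). In acute serum against control it was at -0.0169 without acute 3 and -0.0816 without control 1 (range -0.0816 to 0.321). Depth limits rows near the floor, where a group holds 3 counts or fewer.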

Other observations

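The test of chance separation for miR-7-2-3p was written before its result was seen. The tests on the miR-8908 family and the counts over other splits of the libraries were chosen only after the results were seen.

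The miR-8908 family, a group of 25 rows in these libraries, summed to 29198 ± 11948 CPM in chorioallantois (n = 16), while 9 rows of the miR-506 to miR-514 cluster summed to 1714 ± 640. In endometrium the family ranged from 1343 to 28293 CPM, a range of 21.1-fold, with a median of 29.2% of the chorioallantois mean. The cluster reached at most 1.56% of its chorioallantois mean there, which argues against chorioallantois carried over with the endometrium as the source. Over 8 mares the family's level in endometrium region 1 and region 2 had Pearson's r = 0.66 (permutation p = 0.0772) and Spearman's rho = 0.64 (permutation p = 0.0962), with r = 0.41 after leaving out the 2 mares farthest from the median, so a relation between regions was not shown.

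In acute serum, where eca-miR-8908j-5p was higher than in subacute serum, 9 counts of the miR-506 to miR-514 cluster were found against 190 expected from the miR-8908 family at the chorioallantois ratio. This is 4.74% of the expected number, which argues against RNA released from chorioallantois in the proportions of the tissue as the source in acute serum. The expected number took the whole family, not the rise of eca-miR-8908j-5p alone. Its ratio came from subacute and control tissue, since acute mares gave serum only. In the serum of control 1, by contrast, 25 cluster counts stood beside 366 of the family, where chorioallantois had 5.81 per 100. Serum eca-miR-7-2-3p was at 166 ± 135 CPM in acute, 97.2 ± 54.6 in subacute and 22.01 ± 5.42 in control mares, and all 10 placentitis mares lay above all 3 controls. Counting either direction, 3 rows were separated (eca-miR-30d-3p, eca-miR-598-3p and eca-miR-7-2-3p), against 3.83 by chance (0.699% of rows). Of these, eca-miR-598-3p was lower in placentitis mares. Of 286 splits of the 13 sera, 118 separated as many rows, with up to 31 in another split, so chance was not excluded.

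Other splits of the same libraries were compared with the real count of calls. Taken singly, the share of splits was under 0.05 for endometrium region 1 (1 called, 2 of 56 splits with as many, highest other 1). It was also under 0.05 for acute against subacute serum (4 called, 2 of 100 drawn splits, highest other 7). In each of these 1 other split gave as many calls or more. The shares were not adjusted over the comparisons and the test was chosen after the results were seen, so chance was not excluded there either. For chorioallantois region 1 chance was not excluded (2 called, 13 of 56 splits, highest other 47). That split set subacute 1, 2 and 4 against the rest, which points to a structure among these libraries. Their median correlations with the other chorioallantois libraries were the lowest of that tissue (0.827, 0.910 and 0.927). Subacute 2 had the fewest counts there (236416) and subacute 1 had 9.21% of its counts on other small RNAs. Whether the structure lies in the disease of these mares, in such library traits or elsewhere was not tested. Where 0 were called the count over splits decides nothing, since all 56 of 56 splits give at least 0. Their highest other count was 7 in chorioallantois region 2, 17 in endometrium region 2, 1 in each interaction of region and disease, 3 in that of tissue and disease, 7 in subacute serum and 26 in acute serum against controls. The last split set acute 1, 2 and 3 against the rest. It and the count of 17 also point to structure among the libraries, again of untested origin. Swaps within mares were too few for a share under 0.05 between chorioallantois regions (1 called, 1 of 16, highest other 0), endometrium regions (1 called, 2 of 16, highest other 1) and tissues (318 called, 1 of 4, highest other 0).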
